A study of Rattus norvegicus with 4 samples.

How the data were processed

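The data are 4 reports of 1-colour CodeLink rat arrays, 1 per rat liver, and the value table of the series. Groups and replicate numbers were taken from the labels. Per the file headers, the reports were written by CodeLink Expression Analysis 5.0.0.31312; each gives, as an intensity on a linear scale, the mean signal of a spot, the median of its local background and their difference, and a quality flag. The deposited difference equals spot mean less local background on every spot that was not masked, to within 0.0001. The columns used hold no normalized value. The deposited value table holds intensity values of the same arrays: set against the scanner values, they keep their order on each array (Spearman's rho of 1), have a floor of 0.001 and column medians between 147.483 and 147.506, as quantile normalization of the background-subtracted values gives. How the authors made that table is not given in the sources used here.

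From the spot mean and local background, the background was corrected with normexp and an offset of 50 over all 35129 features. The 1280 control features were then left out and the log2 values of the 33849 gene probes were quantile normalized. Masked spots, between 55 and 67 per array, were missing. Spots flagged as contaminated made up between 1.49% and 7.49% of an array and were kept, as were saturated ones, between 31 and 40 per array. A flag letter of the reports has no stated meaning and is treated with the other quality flags. A probe was kept if it was not flagged as near background on both arrays of at least 1 group, which left 18664 probes. Spiked bacterial control spots differed between the groups by at most 0.11 on the log2 scale.

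Gene names came from the platform annotation, updated through gene identifiers against the GRCr8 RefSeq table: 16753 probes had 1 symbol, 165 had several and were left unnamed, 367 were named through the RefSeq accession in the reports, 13 with conflicting sources were left unnamed, and 16564 have no name here. A listed symbol was matched through an older name only if it is no current symbol of another gene. Where both sources could be compared they gave the same gene for 6725 of 6738 probes. A gene is represented by its brightest kept probe over the 4 arrays, which gave 8985 genes, and alternatives use the same probe where they keep it, a choice made after the data were seen. Of 1999 genes with 2 or more kept probes, 806 had probes of both signs. No coordinates are given.

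Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all kept probes, threshold 0.05), with 2 residual degrees of freedom per probe, 10.8 after moderation, and a median SE of 0.19. Every SE given is the moderated one, which is drawn towards the spread over all probes. A probe not above background on both arrays of 1 group has a bound, written as at least N-fold: the mean of the bright group against the dim group's mean of, per array, the higher of the lowest signal among probes above background and the probe's own. Gene lists, the tests of groups and lists and the rule for named genes were fixed before the data were examined: 42 lists of pathways and cell type markers, of which 36 had at least 5 measured genes. Of 866 symbols on them, 113 had no named probe and were not analysed here. Some single genes on the lists are not reported here. Lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and with the directional test of fry as alternatives. Members were also adjusted over each list alone, with no correction for the number of lists. A pass over the list alone is thus weaker than one over all probes.

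The rule for named genes took, of genes with no overlap between the groups, the 12 with the largest rise and the 12 with the largest fall past the threshold, filled up with the smallest unadjusted p at a log2 difference of at least 1 where fewer passed. It further allows up to 5 members of each list past the threshold and of the carbohydrate and lipid lists, with dehydrogenase kinases and phosphatases and bile acid genes counted among these, every measured thiamine gene, and 3 members of each other list, by the smallest unadjusted p. As none passed, all 24 come from the filling.

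The fit was tested on simulated data for the comparison of thiamine with untreated: 18650 probes with the spread of the real arrays, 200 of them changed, in 5 runs. The changes were divided evenly between 2-fold and 4-fold, with independent noise. It recovered 56% of 2-fold and 99.4% of 4-fold changes, with 10.2 false calls among 166 on average. The 4-fold changes ease the adjusted threshold for the 2-fold ones. The 56% is thus not the share of 2-fold changes that would be called in the real data. The list tests were run on 8977 genes in 60 simulations per setting. Alternatives covered the background correction, an offset of 16, the scaling, the filter, flagged spots, the deposited table, the replicate number as a block, the variance model, array weights, the threshold, the probe per gene, the list test and leaving out each array.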

Results

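Liver RNA of 4 male Otsuka Long-Evans Tokushima Fatty rats, a strain that becomes obese and diabetic on ordinary chow, was measured on 1-colour CodeLink arrays. Thiamine, vitamin B1, had been given in the drinking water of 2 of these rats (0.2%, or 2 g per L) for 51 weeks from 4 weeks of age, and 2 untreated rats drank plain water. The livers were taken at 55 weeks of age after 16 h without food. Each array held 1 rat and no RNA was pooled, and per the labels the study kept 8 rats per group, of which 2 per group were put on arrays; which rats shared a cage is not given in the sources used here. Of 33849 gene probes, 19075 and 20071 were above background on the arrays of thiamine rats 1 and 2, and 18176 and 18392 on those of untreated rats 1 and 2. For arrays, the number of animals limits the precision, and here it is 2 per group, or 1 in a group where a value is given without 1 of the rats. The comparison asks how gene expression in the liver differs after long thiamine intake in this model of obesity.

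No single probe passed the test, so the genes in this paragraph are the most separated ones and not called differences. The NADPH-cytochrome P450 oxidoreductase Por, the electron donor of the microsomal P450 enzymes, was higher in the thiamine livers by 1.29 ± 0.18 (log2, moderated SE, n = 2 per group). Each SE here and below is drawn by limma towards the spread over all probes. For genes whose rats differed widely it is smaller than their own values alone would give. A2m, with an SE of 0.48, was at 9.03 and 11.1 in untreated rats 1 and 2. Noct, a gene with a daily rhythm in liver, was higher by 1.66 ± 0.37, the methyltransferase Inmt by 1.30 ± 0.31 and Vstm4 by 1.36 ± 0.29. The stress-induced transcription factor Atf3 differed by 1.02 ± 0.20, the mitochondrial carrier Slc25a30 by 1.05 ± 0.21, the small GTPase Rab30 by 1.16 ± 0.22, the integrin subunit Itga9 by 1.08 ± 0.20 and the lysosomal phospholipase Pla2g15 by 1.0 ± 0.19. In the other direction, the difference of A2m, an acute phase protein in the rat, was -2.70 ± 0.48 and that of Wfdc21 was -2.10 ± 0.44. The transporters Slc34a2 (-1.42 ± 0.33), Slc28a2 (-1.31 ± 0.26) and Slc22a4 (-1.01 ± 0.19), the water channel Aqp8 (-1.11 ± 0.23), the thymidine phosphorylase Tymp (-1.18 ± 0.25) and the chemokine Cxcl1 (-1.0 ± 0.22) were lower as well. On the array of thiamine rat 1, A2m and Slc22a4 were flagged as contaminated and near background. A2m was at 7.42 and 7.33 in thiamine rats 1 and 2, where the lowest signals above background were 7.09 and 7.11. The size of its difference is thus uncertain. The size of some of these differences rested on 1 rat. Without untreated rat 2 those of A2m, Wfdc21, Slc34a2 and Tymp were -1.66, -1.17, -0.91 and -0.77 and that of Vstm4 was 0.90. Without untreated rat 1 those of A2m and Wfdc21 were -3.76 and -3.03. The difference of Noct was 1.07 without thiamine rat 2 and that of Inmt 0.81 without thiamine rat 1.

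**Figure D1:**
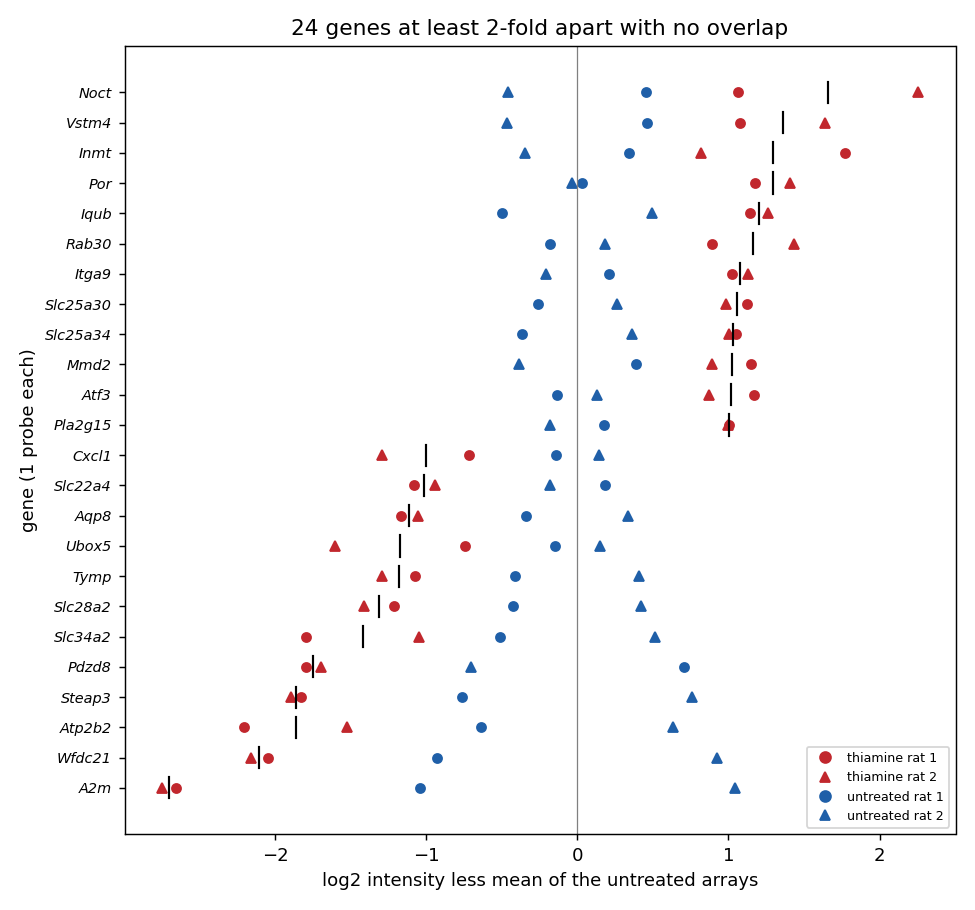
Log2 intensity of 24 genes on each of the 4 arrays, less the mean of the 2 untreated arrays of that gene; red symbols are thiamine rats, blue symbols untreated rats, circles rat 1 and triangles rat 2, and the black bar is the difference of the group means. The difference runs from -2.70 for A2m to 1.66 for Noct, and none of the 24 passed the test.

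Some of the separated genes were measured in 1 group only. Slc25a34, Iqub and Mmd2 were not well above background on either untreated array and were at least 1.46-fold, 1.35-fold and 1.48-fold higher in the thiamine livers. Atp2b2, Steap3, Pdzd8 and Ubox5 were not well above background on either thiamine array and were at least 2.87-fold, 2.77-fold, 2.19-fold and 1.81-fold higher in the untreated livers. The bounds of Atp2b2, Steap3 and Pdzd8 rested on single rats. Without untreated rat 2 they were 1.87-fold for Atp2b2, 1.67-fold for Steap3 and 3.64-fold for Pdzd8, and without untreated rat 1 they were 4.51-fold, 4.76-fold and 1.35-fold. Those of Slc25a34, Iqub, Mmd2 and Ubox5 stayed between 0.91 and 1.11 times the bound with all arrays when 1 array was left out. The adjusted p of limma over these 24 genes lay between 0.22 and 0.27.

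Over all 18664 kept probes, limma with Benjamini-Hochberg adjustment called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.22. At an unadjusted p under 0.05 there were 1260 probes, 711 higher and 549 lower in the thiamine livers, where 933 would be expected by chance. This balance turned under other settings: 570 were higher and 610 lower with median scaling, 828 and 931 with no filter on dim probes, 500 and 503 among probes above background on all 4 arrays, and 1002 and 1113 without untreated rat 1. At least 2-fold apart with no overlap between the groups were 74 probes, 44 higher and 30 lower, of which 44 carried a gene name. Regrouping the same 4 arrays so that each side held 1 rat of each group gave 17 and 18 such probes, and 523 and 752 at an unadjusted p under 0.05 (limma). No further regrouping of this kind exists, so by chance alone the real grouping would rank highest in 33.3% of cases. Of all probes, 36.1% had groups that did not overlap, against 27.9% and 35.9% in these regroupings and 33.3% by chance for 2 against 2. Leaving out 1 array moved these counts: without thiamine rat 1 the test called 2 probes and 137 were 2-fold apart, without thiamine rat 2 it called 87 with 297 apart, without untreated rat 1 it called 83 with 302 apart, and without untreated rat 2 it called 74 with 290 apart. A group with 1 array cannot overlap itself, so these separations are easier to reach, and the lone rat is assumed to vary like the other group.

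The genes closest to the treatment itself did not move in 1 direction as a list. Of the 24 genes listed before the data were examined for thiamine transport and thiamine-dependent enzymes, 15 were measured, 7 higher and 8 lower, with a median difference of -0.02 and a mean of 0.03, so that the median differs in sign from the mean and from the direction of the test; it was 0.031 without thiamine rat 2 and 0.030 without untreated rat 1 or untreated rat 2. The thiamine-dependent lyase Hacl1 was higher by 0.44 ± 0.20, or 0.22 without untreated rat 2 and 0.67 without untreated rat 1, while the pyruvate dehydrogenase component Dlat was at -0.41 ± 0.18 and the oxoglutarate dehydrogenase component Dlst at -0.29 ± 0.18. The transketolase gene Tkt was at -0.03 ± 0.21, and at 0.18 without thiamine rat 2 and 0.12 without untreated rat 2, but -0.25 without thiamine rat 1 and -0.18 without untreated rat 1. None passed the test adjusted over all probes, nor adjusted over the list alone, and the list as a whole did not pass (camera, adjusted p = 0.87). Opposite directions cancel in the median and in camera. At an unadjusted p under 0.05 (limma) 2 of the 15 genes were higher and 1 lower, against 1260 of all 18664 kept probes. The test of fry for changes in either direction did not pass (adjusted p = 0.41).

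Regulators of pyruvate and glucose use were apart in both directions, without passing over all probes. Pdk4, a kinase that switches off pyruvate dehydrogenase, was higher by 0.82 ± 0.19 and its counterpart phosphatase Pdp2 by 0.50 ± 0.19, and Pdk2 was at -0.54 ± 0.18, although 1 of the 3 probes of Pdk2 was higher. Their list also holds the kinase and the phosphatase of the branched-chain ketoacid dehydrogenase, of which the phosphatase Ppm1k was higher by 0.59 ± 0.22. Pdk4 was the 1 of 9 measured members of this list that passed adjusted over the list alone. That adjustment, here and below, does not correct for the number of lists. Gckr was at -1.06 ± 0.27 and the liver pyruvate kinase Pklr at -0.43 ± 0.19. Without untreated rat 2 the difference of Gckr was -0.61. Without thiamine rat 2 those of Ppm1k and Pklr were 0.28 and -0.27, and without thiamine rat 1 that of Ppm1k was 0.90. Among 25 measured genes of glycolysis 11 were higher and 14 lower, and of 18 genes of gluconeogenesis and glycogen 10 were higher and 8 lower, with Ugp2 at 0.56 ± 0.22 (0.24 without untreated rat 2 and 0.88 without untreated rat 1) and Pgm1 at -0.50 ± 0.18. Pygb, a glycogen phosphorylase, was not well above background in the untreated livers and was at least 1.31-fold higher with thiamine. In the pentose phosphate pathway 2 of 11 genes were higher and 9 lower, and in the tricarboxylic acid cycle 6 of 15 were higher and 9 lower. None of these lists passed (camera, adjusted p = 0.58 for the list of these kinases and phosphatases, 0.87 for glycolysis, 0.85 for gluconeogenesis and glycogen, 0.41 for the pentose phosphate pathway and 0.50 for the tricarboxylic acid cycle).

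Genes of cholesterol synthesis were higher as a list. Of 23 measured members 16 were higher and 7 lower, with a median of 0.24 (camera, adjusted p = 0.048, and adjusted p = 0.85 with an estimated correlation), and 0 passed adjusted over the list alone. The sterol demethylase Cyp51 was higher by 0.48 ± 0.18, Msmo1 by 0.57 ± 0.22 and Tm7sf2 by 0.65 ± 0.27, while the mevalonate decarboxylase Mvd was at -0.61 ± 0.21. Without untreated rat 1 Msmo1 was at 0.30 and Tm7sf2 at 1.12, and without untreated rat 2 Tm7sf2 was at 0.18 and Mvd at -0.38. With the correlation between genes estimated from the data the call was lost. That version called 0% of simulated lists shifted by 0.5, so a call lost with it, here or for the lists below, does not weigh against a list. The power of fry was not simulated. The call was also lost without thiamine rat 1 (median 0.074) and without untreated rat 1 (median 0.043), and the median was 0.36 without untreated rat 2. It was kept under 8 of 18 alternatives, over which the adjusted p ran from 0.0048 to 0.85.

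Other lipid genes went both ways. Of 35 measured genes of fatty acid oxidation 17 were higher and 18 lower: the carnitine palmitoyltransferases Cpt1a and Cpt2 were at 0.54 ± 0.20 and 0.47 ± 0.20, Ehhadh at 0.52 ± 0.22 and Etfdh at -0.64 ± 0.18. Of 21 genes of fatty acid and triglyceride synthesis 7 were higher and 14 lower, with Fads2 at 0.66 ± 0.22, Lpin2 at 0.43 ± 0.18 and Elovl5 at -0.57 ± 0.18. The 6 measured genes of ketone body synthesis were all lower, with a median of -0.19 (camera, adjusted p = 0.15), and this median was 0.025 without untreated rat 2 and -0.43 without untreated rat 1, where the list passed (adjusted p = 0.0053). The phospholipid transfer protein Pltp was higher by 0.78 ± 0.20 and passed adjusted over its list alone, the lipase Pnpla2 was at 0.59 ± 0.21, the lipid droplet protein Hilpda at 0.61 ± 0.20 and Fabp2 at -0.99 ± 0.31, or -0.40 without untreated rat 2 and -1.60 without untreated rat 1. Without untreated rat 1 the values of Cpt1a, Cpt2 and Pnpla2 were 0.36, 0.29 and 0.37. That of Ehhadh was 0.24 without thiamine rat 2 and 0.82 without thiamine rat 1, and that of Fads2 was 0.37 without untreated rat 2. In bile acid metabolism the repressor Nr0b2 was at -0.82 ± 0.21 and passed adjusted over its list alone, Cyp27a1 at 0.45 ± 0.19 and Amacr at 0.46 ± 0.20, or 0.30 and 0.29 without untreated rat 2. None of these lists passed (camera, adjusted p = 0.87 for fatty acid oxidation, 0.38 for fatty acid and triglyceride synthesis, 0.87 for lipoproteins, 0.19 for lipid droplet genes and 0.43 for bile acid genes).

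Genes of xenobiotic and steroid metabolism and of amino acid metabolism were higher in the thiamine livers as lists. For the xenobiotic list 22 of 30 measured members were higher and 8 lower, with a median of 0.28 (camera, adjusted p = 0.00023, and adjusted p = 0.85 with an estimated correlation), led by Por, the 1 member that passed adjusted over the list alone, Ugt2b1 (0.83 ± 0.26), Fmo5 (0.67 ± 0.20), Cyp3a9 (0.62 ± 0.23) and Cyp3a18 (0.54 ± 0.22). The probes of the Cyp3a and Ugt2b families may not tell copies apart. For amino acid and urea cycle metabolism 21 of 32 were higher and 11 lower, with a median of 0.25 (camera, adjusted p = 0.0064, and adjusted p = 0.85 with an estimated correlation). Of its members the argininosuccinate lyase Asl (0.91 ± 0.18) passed adjusted over the list alone, and Sds (0.98 ± 0.28), Prodh (0.71 ± 0.19) and the carbamoyl phosphate synthase Cps1 (0.53 ± 0.18) were higher while Cth was at -0.54 ± 0.18. Without untreated rat 1 Ugt2b1, Cyp3a9 and Cyp3a18 were at 0.42, 0.26 and 0.86, and without untreated rat 2 Cyp3a9, Cyp3a18 and Sds were at 0.98, 0.24 and 0.55. Without thiamine rat 2 the xenobiotic list had a median of 0.21 (adjusted p = 0.057) and the amino acid list one of 0.17 (adjusted p = 0.13). Without untreated rat 2 the amino acid list had 0.12 (adjusted p = 0.068). Over 18 alternatives the adjusted p ran from 3.0e-05 to 0.85 for the xenobiotic list and from 0.0018 to 0.85 for the amino acid list.

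Acute phase and endoplasmic reticulum genes were lower as lists. Of 26 measured genes of the acute phase and complement 20 were lower and 6 higher, with a median of -0.18 (camera, adjusted p = 0.0019, and adjusted p = 0.85 with an estimated correlation). A2m and the lipopolysaccharide-binding protein Lbp (-0.69 ± 0.18) passed adjusted over the list alone, Mbl1 was at -0.49 ± 0.18 and Stat3 at -0.50 ± 0.20, and Hamp, the iron hormone hepcidin, was higher by 0.52 ± 0.19. For endoplasmic reticulum stress 14 of 22 were lower and 8 higher, with a median of -0.20 (camera, adjusted p = 0.041, and adjusted p = 0.85 with an estimated correlation). The folding factors Sdf2l1 (-0.89 ± 0.21), Manf (-0.79 ± 0.22), Hspa5 (-0.56 ± 0.19) and Pdia4 (-0.51 ± 0.18) were lower while Atf3 was higher, and Sdf2l1, Manf and Atf3 passed adjusted over the list alone. A2m was at -1.66 without untreated rat 2, and Stat3 at -0.30 and Manf at -0.51 without untreated rat 1. Without untreated rat 2 the acute phase list had a median of -0.12 (adjusted p = 0.052) and the endoplasmic reticulum list one of -0.17 (adjusted p = 0.75). The latter was lost without thiamine rat 1 (-0.22, adjusted p = 0.12) and thiamine rat 2 (-0.16, adjusted p = 0.062) too. Over 18 alternatives the adjusted p of the list tests ran from 0.00012 to 0.85 for the acute phase list. The endoplasmic reticulum list was kept under 8 of 18. With all 4 arrays it was lost with background-subtracted intensities, no filter on dim probes and only probes above background on all arrays. The same held with flagged spots set to missing, the deposited table and the directional test of fry. The list was also lost with an estimated correlation, which called 0% of simulated lists shifted by 0.5.

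**Figure D2:**
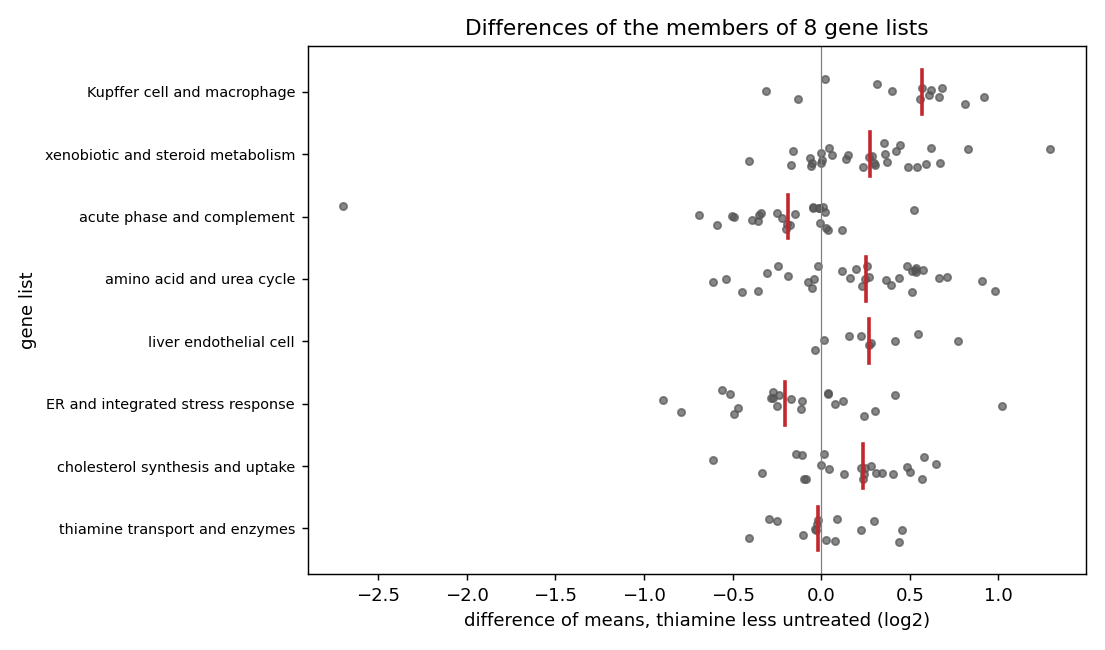
Difference of group means (thiamine less untreated, log2) of each measured member of 8 gene lists, as grey points, with the list's median as a red bar; the vertical spread of the points has no meaning. The medians run from -0.20 for the endoplasmic reticulum list to 0.57 for the macrophage list, and that of the thiamine list is -0.02.

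Markers of macrophages and of the liver endothelium were higher in the thiamine livers, beside the metabolic lists above. Of 13 measured markers of Kupffer cells, the resident macrophages of the liver, 11 were higher and 2 lower, with a median of 0.57 (camera, adjusted p = 0.00023, and adjusted p = 0.85 with an estimated correlation). The protease Ctss (0.92 ± 0.25) and the complement genes C1qa (0.81 ± 0.24), C1qc (0.68 ± 0.24) and C1qb (0.67 ± 0.21) passed adjusted over the list alone. The estimated correlation between members of this list was 0.70, so these passes are not independent of each other. The scavenger receptor Cd163 was at 0.61 ± 0.24. Of 9 endothelial markers 8 were higher and 1 lower, with a median of 0.27 (camera, adjusted p = 0.0088, and adjusted p = 0.85 with an estimated correlation), among them Lyve1 (0.77 ± 0.20), the 1 that passed adjusted over the list alone, Pecam1 (0.55 ± 0.18) and Kdr (0.42 ± 0.20). Ctss, C1qa, C1qc and Cd163 were at 0.57, 0.52, 0.32 and 0.26 without thiamine rat 1, and C1qb and Kdr at 0.44 and 0.20 without untreated rat 2. Without thiamine rat 2 C1qc and Cd163 were at 1.05 and 0.96, and without untreated rat 1 Kdr was at 0.64. Within the groups the macrophage markers differed by a median of 0.64 between the thiamine rats and 0.44 between the untreated rats. Without thiamine rat 1 the macrophage and endothelial medians were 0.26 (adjusted p = 0.26) and 0.16 (adjusted p = 0.12), and without untreated rat 2 they were 0.25 (adjusted p = 0.16) and 0.25 (adjusted p = 0.068). Over 18 alternatives the adjusted p ran from 1.3e-11 to 0.85 and from 0.0044 to 0.85. The 9 hepatocyte markers had a median of -0.04 (camera, adjusted p = 0.90), or 0.034 without thiamine rat 1 and -0.11 without thiamine rat 2. Their member Ahsg was saturated on all 4 arrays, so the size of its difference (-0.18 ± 0.18) is uncertain. The 7 stellate cell markers had a median of 0.09 (camera, adjusted p = 0.41), or -0.19 without untreated rat 2 and 0.24 without untreated rat 1.

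**Figure D3:**
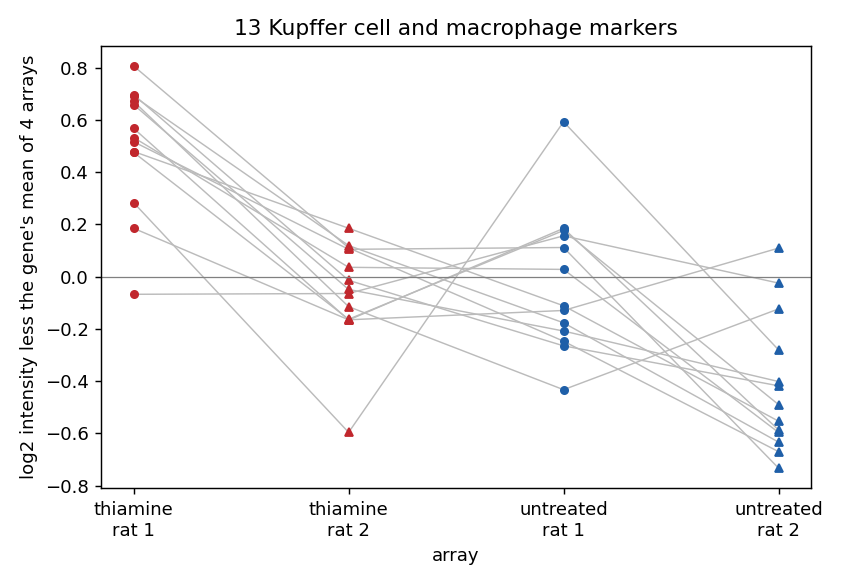
Log2 intensity of 13 Kupffer cell and macrophage markers on each array, less the gene's mean over the 4 arrays; grey lines join the values of 1 gene, red symbols are thiamine rats and blue symbols untreated rats. Thiamine rat 1 lies above thiamine rat 2 for 12 of the 13 markers, and untreated rat 1 above untreated rat 2 for 11 of 13.

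Of the 36 lists tested, 7 passed with camera's preset correlation between genes, 5 higher and 2 lower, and 0 passed with an estimated correlation or with the directional test of fry, whose smallest adjusted p was 0.54; at an unadjusted p under 0.05 these gave 0 and 3 lists. The test of fry for changes in either direction passed 1 list, the immediate early genes (adjusted p = 0.048). Without thiamine rat 1 the preset correlation called 3 lists. The median differed in sign from the mean and the test for the thiamine list, the hepatocyte list (mean 0.06), the immediate early list (median -0.03, mean 0.11, adjusted p = 0.51) and the list of advanced glycation and aldose reductase (median -0.012, mean 0.065, adjusted p = 0.70). The mean differed from the median and the test for fatty acid oxidation (mean 0.011, median -0.012), lipoproteins (mean 0.0069, median -0.025) and skeletal muscle (mean 0.022, median -0.082, adjusted p = 0.87). In simulated data with the spread of these arrays, the preset correlation called on average 0.05 of 35 unshifted lists where genes varied independently. It called 10.9 of 35 where they shared a correlation of 0.3 and 16.7 of 35 at 0.6. In the real data the estimated correlation was 0.70 for the macrophage list. For the other lists that passed it lay between -0.03 (acute phase) and 0.19 (cholesterol). The estimated correlation called 0% of lists shifted by 0.5, so with 2 rats per group neither version settles a list. Arrays of 1 group differed by a median of 0.16 (thiamine) and 0.22 (untreated) on the log2 scale, and arrays of different groups by between 0.17 and 0.22.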

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

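No probe passed at an adjusted p under 0.05 with 2 rats per group under any of the other scalings, filters, variance models or value sources, where the smallest adjusted p lay between 0.064 and 0.95. The exceptions were the replicate block, with 126 probes, and leaving out 1 array, with between 2 and 87. An unadjusted p under 0.01 gave 384 probes, where 187 would be expected by chance and the regroupings of the same arrays gave 87 and 83. The replicate number of the labels as a block leaves 1 degree of freedom; rats with the same number did not deviate together (correlation of -0.074 over probes), so the numbers are not taken to pair the rats, and the block left the count of lists at 7.

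The count of probes at least 2-fold apart, 74, was 151 with an offset of 16, which shrinks dim probes less, 195 with no filter and 36 with only probes above background on all 4 arrays. It lay between 137 and 302 when 1 array was left out. The balance of 44 higher and 30 lower turned with median scaling (35 and 38), background-subtracted intensities (44 and 48), no filter (86 and 109) and the deposited table (45 and 49); the cause was not tested. It turned as well without untreated rat 1 (125 and 177) and untreated rat 2 (98 and 192). The count of lists, 7, was between 5 and 7 under the other processing settings with all arrays, 0 with an estimated correlation and 0 with the directional test of fry, and between 3 and 10 with 1 array left out.

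Of 1571 values of 93 named genes over the alternatives, 1569 kept their direction. The exceptions were Tkt without thiamine rat 2 and without untreated rat 2, with a range over the arrays left out of -0.25 to 0.18. Many of the kept directions were fixed in advance. A gene with no overlap between the groups can hardly turn when 1 array is left out. The block, the variance models and the array weights leave the difference of a gene as it was. Of the 93 genes, 44 moved by over 1.5 times or turned without 1 of the arrays. Leaving out 1 array also turned list medians that had not passed: thiamine genes -0.051 to 0.031, hepatocyte markers -0.11 to 0.034, stellate cell markers -0.19 to 0.24, interferon genes -0.28 to 0.11, ketone body genes -0.43 to 0.025 and oxidative phosphorylation -0.21 to 0.043. The 7 lists that passed kept the sign of their median under all 18 alternatives each. The block, the variance model, the array weights and the list test do not change a median, so these alternatives could not turn it. The spread between replicates stayed between 0.17 and 0.24, against 0.19.

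The columns used hold no normalized intensity and each array is a slide of its own with no scan day given, so the alternatives with these were not run; robust hyperparameters have no counterpart in camera. Signal over background limits the dim probes: between 53.7% and 59.3% of gene probes were above background.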

Other observations

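The tests of explanations below were chosen after the result was seen, except that of the glucocorticoid genes.

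Genes outside the metabolic lists were apart as well, none past the threshold over all probes. In the insulin and growth hormone list 14 of 20 measured genes were higher, with a median of 0.14 (camera, adjusted p = 0.14), or 0.084 without thiamine rat 1 and 0.091 without thiamine rat 2, led by Igfbp3 (0.91 ± 0.18), which carries insulin-like growth factors, Irs2 (0.65 ± 0.20) and Cish (0.42 ± 0.19). The small heat shock protein Hspb1 was higher by 1.0 ± 0.25 (0.63 without thiamine rat 2) and the aldose reductase Akr1b1 by 0.61 ± 0.18, while the immediate early gene Egr1 was at -0.77 ± 0.18. Of 23 interferon genes 15 were lower, with a median of -0.09 (adjusted p = 0.15), or 0.11 without untreated rat 1 and -0.28 without untreated rat 2 (adjusted p = 0.018), among them Irgm (-0.82 ± 0.20), Psmb9 (-0.70 ± 0.19) and Irf1 (-0.54 ± 0.19). Of 37 genes of oxidative phosphorylation 23 were lower, with a median of -0.07 (adjusted p = 0.14), or 0.043 without untreated rat 2 and -0.21 without untreated rat 1 (adjusted p = 0.00094), and Ndufv1 was at -0.48 ± 0.18. The 8 genes of antigen presentation had a median of 0.31 (adjusted p = 0.23), which was 0.045 without thiamine rat 1 and 0.0033 without untreated rat 2; the list passed without thiamine rat 2 (0.58, adjusted p = 0.0068) and without untreated rat 1 (0.64, adjusted p = 0.0063).

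The macrophage markers were higher in the thiamine livers by a median of 0.57. A lower share of hepatocytes would raise the markers of all other cell types alike. The macrophage median was 0.41 above that of 36 markers of 6 other types (bootstrap interval over genes 0.082 to 0.58). This interval treats genes as independent, though the estimated correlation within the macrophage list was 0.70. It does not measure the spread between rats, so it cannot decide whether a lower share of hepatocytes was the whole cause. The gap rested on thiamine rat 1 and untreated rat 2, without which it was 0.18 and 0.20. A candidate explanation is that macrophage content varies between single rats: the markers differed by a median of 0.64 between the thiamine rats, more than between the groups. With 2 rats per group that stays open, as does an effect of thiamine, which was not tested apart from it.

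The acute phase list was lower by a median of -0.18, and A2m was at 9.03 in untreated rat 1 and 11.1 in untreated rat 2 (log2 intensity). An acute phase response in untreated rat 2 alone, weighed as a candidate explanation, would put untreated rat 1 beside the thiamine rats, so that over the list rat 1 less rat 2 would be 2 times the group median, or -0.37. Over the 26 genes it was 0.016, which is above that by 0.39 (bootstrap interval over genes 0.013 to 0.70). This interval treats genes as independent and does not measure the spread between rats. It therefore cannot decide for or against such a response in 1 rat. Without thiamine rat 2 the gap was 0.28, and against untreated rat 1 alone the thiamine median was -0.11. Variation between single rats and an effect of thiamine stay open, as neither was tested apart from the other.

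Of 15 measured clock genes 9 were higher and 6 lower, with a median of 0.13, and the list did not pass (camera, adjusted p = 0.38). Opposite directions cancel in the median and in camera, so these cannot decide whether the clock genes moved. The test of fry for changes in either direction did not pass (adjusted p = 0.21). Cry1, Bmal1, Per1 and Per2 passed adjusted over the list alone. Per2 (0.79 ± 0.19) and Cry1 (0.83 ± 0.21) were higher. Bmal1 was at -1.0 ± 0.30, or -0.43 without untreated rat 2 and -1.58 without untreated rat 1. Sampling at different times of day may be a cause, as the hour is not in the labels used here. The test assumed that it would move 5 genes of an early phase, chosen after the values were seen, in 1 direction. This need not hold where their daily peaks lie at different hours, so their directions do not weigh against it. They went both ways: Nr1d1 (-0.45 ± 0.18), Per3 (-0.25 ± 0.20) and Tef (-0.021 ± 0.22) were lower and Nr1d2 (0.23 ± 0.18) and Dbp (0.43 ± 0.35) higher. As only 1 of them differed by over 2 standard errors, tissue taken at different times of day stays open. A stronger glucocorticoid signal was tested on genes named beforehand: 6 of 8 measured were higher, with a median of 0.22 (bootstrap interval -0.071 to 0.42), at a camera p of 0.033, or 0.16 with an estimated correlation. This rests on the make-up of the set, since a first draft with 3 further genes, dropped before the test because they stood on the fixed lists (1 had a value already seen), gave a median of 0.11 and a p of 0.12 over 11 genes, so it is left open.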
